A study of Mus musculus with 12 samples.

How the data were processed

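Total RNA of mouse vessels was measured on 12 Affymetrix arrays, 3 described as biological replicates at each of day 0, 1, 3 and 7 of angiotensin II. The deposited table holds log2 signals that the authors had summarised per transcript cluster with Affymetrix Expression Console, per the submitters' processing notes. The version, the background correction and the normalization are not given in the sources used here. The labels name an earlier Affymetrix mouse genome array, but the feature identifiers are transcript clusters with control features of another Affymetrix design, so the table's own identifiers and annotation were used. The scale ends at a ceiling that 581 of the 72688 features reach on all arrays, and a fold change that starts or ends there is a bound. Of the features 65956 were transcript clusters: 31258 with 1 gene symbol, 1492 with several and 33206 with none. Clusters with several symbols were left out, those with none were tested apart, and the 6732 control features served as quality signs.

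Values were used as deposited, with no further normalization. For each of 30702 genes the transcript cluster with the highest mean over the 12 arrays was taken, and genes were kept when at least 3 of 12 arrays reached the 40th percentile of all transcript clusters (5.25), which left 22065. Genes were tested in R 4.3.3 with limma 3.58.1: a mean per group, all 12 arrays in the fit, empirical Bayes without trend, and Benjamini-Hochberg adjusted p under 0.05 for a call. Days 1, 3 and 7 were compared with day 0, day 3 with day 1 and day 7 with day 3, and the F test covered the 3 contrasts against day 0. The 40 gene lists were tested with camera at a preset correlation of 0.01, with the correlation estimated per list, and with fry, each adjusted over the lists of a comparison. Members were also adjusted over the list alone. These choices, the lists and the alternatives were fixed before the data were examined, except 4 alternatives added after seeing the data: constant genes left out, protein-coding genes only, gene-by-gene array weights, and the difference between positive and negative control features as a covariate.

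Genes were named by a fixed rule. Against day 0 they are the 12 with the largest change in each direction among those called whose 3 treated arrays all lay beyond the 3 day 0 arrays, and between treated days the 6 largest. Symbols of predicted or clone-like genes were passed over. Each list adds up to 4 called members with the largest change, of which the text gives a selection, and 10 genes of the angiotensin response were looked up in every comparison. Alternatives were quantile normalization, median centring, no filter, a stricter filter at the 60th percentile, the mean of a gene's features, all features, variance trend with robust estimation, the replicate number as a factor, covariates for adipocyte and skeletal muscle signal, leaving out each array, and a fit on the 6 arrays compared. The method was tested on simulated data with known changes in 200 of 22065 genes: 56, 67 and 60% of changes of 1 log2 unit and 92, 88 and 88% of changes of 2 units were recovered for days 1, 3 and 7, with 5, 9 and 6 false calls. A cell cycle list shifted by 1 log2 unit was called with adjusted p = 8.89e-59, 6.75e-60 and 3.49e-63 in camera, and adjusted p = 3.16e-06, 3.23e-05 and 2.38e-06 with an estimated correlation, and 0 of the other lists were called. The simulated errors were drawn independently for each gene, so these tests say nothing of false calls among correlated genes. Exact permutation tests were used for array quality.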

Results

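Gene expression was measured by microarray in total RNA of mouse vessels at 4 times of angiotensin II infusion. Angiotensin II is the peptide hormone of the renin-angiotensin system that constricts arteries and raises blood pressure, and it was given by osmotic pump at 1500 ng per kg per min. Male C57BL/6 mice aged 8 to 10 weeks were studied untreated (day 0) and after 1, 3 and 7 days of infusion, with 3 arrays per group described as biological replicates and 12 arrays in all. The day 0 mice were untreated, and a vehicle pump is not given in the sources used here, so pump surgery and angiotensin II were not separated by the design. Which vessel was taken, and with how much of the surrounding tissue, is not given in the sources used here either. The table held 72688 features on the log2 scale, and 22065 genes passed the filter on dim signals and were tested. Pearson r between arrays of a group lay between 0.974 and 0.993, and the number of arrays limits the precision of every estimate. Correlations between groups overlapped this range. Day 1 replicate 1 correlated at 0.989 to 0.991 with the day 3 arrays, and at 0.987 and 0.977 with day 1 replicates 2 and 3.

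Signal over background differed between the groups. The median of the positive control features minus that of the negative control features averaged 2.59 ± 0.05 log2 units at day 0, 2.25 ± 0.29 at day 1, 1.98 ± 0.14 at day 3 and 1.76 ± 0.49 at day 7 (SD, n = 3 each). It was below all day 0 arrays on each of the 9 treated arrays and lowest, at 1.20, on day 7 replicate 1. The exact two-sided permutation test of each treated group against day 0 gave p = 0.1, the smallest that 3 against 3 arrays allow. Poly-A spike controls were also below all day 0 arrays on each of the 9 treated arrays. A difference in how the arrays were processed was therefore not separated from infusion in the comparisons with day 0. At day 7 genes with a mean signal between 5 and 6 had a median log2 change of 0.25 against day 0, and genes between 10 and 12 had -0.36. Small nuclear and nucleolar RNA genes, 1573 of the 22065 tested, made up 114 of the 439 genes that rose at day 1, 247 of 1018 at day 3 and 449 of 2668 at day 7. At day 0, 7306 of the 22065 genes lay under the negative control median of their array on all 3 arrays. Of the changed genes named below, Col8a1, Il6, Kif11, Ccl12, Prc1, Ccl8, Ifit1, Irf7, Myh6, Myl7 and Saa3 (day 0), C1qtnf3 and Myh6 (day 3) and Hlf (day 1) did so in the dimmer group. Background compresses such fold changes and the shift of dim genes adds to their rises, so their sizes are approximate, and dim genes or lists that did not pass may have changed unseen.

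**Figure D1:**
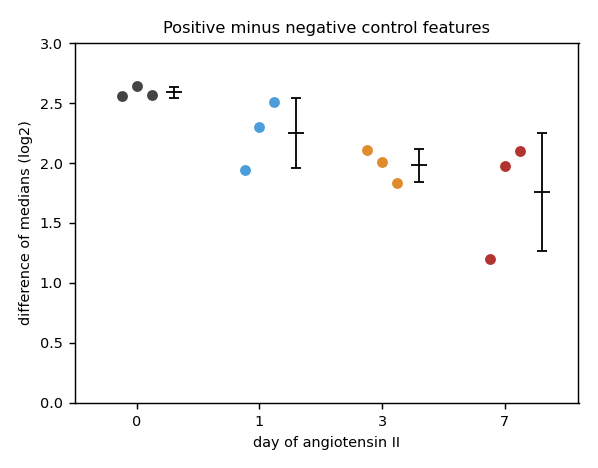
Difference between the medians of positive and negative control features (y axis, log2) by day of angiotensin II (x axis), with a point per array and the group mean with its SD as a black bar beside the points. All 9 treated arrays lie below the 3 day 0 arrays, which sit between 2.56 and 2.64, and the lowest array is day 7 replicate 1 at 1.20.

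The first comparison asked what had changed in the vessel after 1 day of infusion. The macrophage, cell cycle, chemokine and collagen lists were higher, and the brown adipocyte, oxidative phosphorylation and contractile lists were lower, but these calls did not hold with an estimated correlation (adjusted p = 0.273 to 0.45 with an estimated correlation). Prg4, the joint and tissue lubricant lubricin, rose by 5.49 ± 0.93 log2 units (± SE of the limma estimate here and for every fold change below, n = 3 arrays per group). Serpina3n, an acute-phase protease inhibitor, rose by 5.15 ± 0.88 and Esm1, a proteoglycan secreted by activated endothelium, by 4.48 ± 0.38. Hspa1a, the inducible heat shock protein 70, changed by -5.95 ± 0.71, and Ucp1, the uncoupling protein of brown fat, by -5.45 ± 1.27.

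Among the other genes that rose most were the mitosis marker Mki67 (3.65 ± 0.49), the macrophage mannose receptor Mrc1 (3.50 ± 0.54), the macrophage lysozyme Lyz2 (3.11 ± 0.38) and the inhibitory myeloid receptor Lilrb4a (2.89 ± 0.52). Matrix genes in that set were the fibril-associated collagen Col12a1 (3.57 ± 0.61), the short-chain collagen Col8a1 (2.79 ± 0.45), the stromelysin protease Mmp3 (3.17 ± 0.32) and the adhesion protein Svep1 (2.81 ± 0.30). The small nucleolar RNA Snord14e rose by 3.45 ± 0.61. Genes that fell included Pi15 (-4.09 ± 0.48), a secreted CRISP-family protein, Ccdc3 (-3.51 ± 0.76), a secreted protein of fat and endothelium, and Cpe (-3.06 ± 0.70), carboxypeptidase E. The sorting receptor Sorl1 (-3.02 ± 0.40), the desmosomal protein Dsp (-2.98 ± 0.48), the matrix protein Ecm2 (-2.91 ± 0.43), the glutathione transferase Gstm1 (-2.73 ± 0.41), Lgr6 (-2.70 ± 0.43), a receptor for R-spondins, and Fbxo30 (-2.64 ± 0.37), a ubiquitin ligase subunit, fell as well. Gucy1b1, the beta subunit of the nitric oxide receptor guanylate cyclase, changed by -2.63 ± 0.42. Adjusted p in limma ran from 0.0014 to 0.0493 over these 24 genes, and the 3 treated arrays lay beyond all 3 day 0 arrays for each.

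At day 1, of 26 cell cycle genes measured, 13 rose and 13 did not pass, while 24 rose adjusted over the list alone. Top2a stood at 2.25 ± 0.31 and the mitotic kinesin Kif11 at 1.81 ± 0.24. Cell cycle genes had a median change of 0.66 and gave camera adjusted p = 6.93e-22, but adjusted p = 0.273 with an estimated correlation. Of the 26, 18 lay under the negative control median on all day 0 arrays, so the size of the list's change from day 0 is approximate here and at days 3 and 7. Of 21 monocyte and macrophage genes measured, 9 rose and 12 did not pass, while 17 rose adjusted over the list alone. The lysosomal protein gene Cd68 (1.87 ± 0.36) and the complement component C1qb (1.71 ± 0.37) were among them. Macrophage genes had a median change of 1.09 and gave camera adjusted p = 2.64e-13, but adjusted p = 0.273 with an estimated correlation. Of 21 chemokine genes measured, 6 rose and 15 did not pass, while 7 rose adjusted over the list alone. Ccl7 stood at 2.48 ± 0.40, Ccl6 at 2.20 ± 0.33 and the monocyte attractant Ccl2 at 1.99 ± 0.36. Chemokines had a median change of 0.48 and gave camera adjusted p = 1.84e-05, but adjusted p = 0.273 with an estimated correlation. Of 10 leukocyte adhesion genes measured, 3 rose and 7 did not pass, while 7 rose adjusted over the list alone. The integrin subunit Itgam stood at 1.83 ± 0.30. Adhesion genes had a median change of 0.66 and gave camera adjusted p = 2.74e-05, but adjusted p = 0.273 with an estimated correlation. Of 26 collagen and matrix structure genes measured, 6 rose and 20 did not pass, while 8 rose adjusted over the list alone. The crosslinking enzyme Lox stood at 2.59 ± 0.36 and Col6a3 at 1.89 ± 0.22. Collagen genes had a median change of 0.48 and gave camera adjusted p = 4.07e-06, but adjusted p = 0.273 with an estimated correlation. Of 18 matrix proteases and inhibitors measured, 4 rose and 14 did not pass, while 9 rose and 1 fell adjusted over the list alone. The inhibitor Timp1 rose by 2.41 ± 0.40 and the urokinase Plau by 1.34 ± 0.19. Matrix proteases had a median change of 0.52 and gave camera adjusted p = 6.03e-05, but adjusted p = 0.273 with an estimated correlation. Of 17 unfolded protein response genes measured, 3 rose and 14 did not pass, while 7 rose adjusted over the list alone. The disulfide isomerase Pdia6 rose by 2.03 ± 0.43. Unfolded protein response genes had a median change of 0.59 and gave camera adjusted p = 0.000104, but adjusted p = 0.45 with an estimated correlation.

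At day 1, of 25 oxidative phosphorylation genes measured, 2 fell and 23 did not pass, while 16 fell adjusted over the list alone. Cox5a stood at -0.73 ± 0.16 and Cox4i1 at -0.62 ± 0.11. Oxidative phosphorylation genes had a median change of -0.50 and gave camera adjusted p = 6.03e-12, but adjusted p = 0.273 with an estimated correlation. Of 14 brown adipocyte genes measured, 1 rose, 4 fell and 9 did not pass, while 1 rose and 9 fell adjusted over the list alone. Dio2, the deiodinase that activates thyroid hormone, rose by 2.01 ± 0.45, and the fatty acid carrier Fabp3 changed by -1.49 ± 0.30. Brown adipocyte genes had a median change of -0.84 and gave camera adjusted p = 3.33e-07, but adjusted p = 0.273 with an estimated correlation. Of 17 circadian clock genes measured, 1 rose, 5 fell and 11 did not pass, while 1 rose and 11 fell adjusted over the list alone. The repressor Nr1d1 stood at -1.88 ± 0.41, the output factor Dbp at -1.73 ± 0.33 and Hlf at -1.32 ± 0.15. Clock genes gave camera adjusted p = 1.43e-06, but adjusted p = 0.273 with an estimated correlation. Of 19 contractile smooth muscle genes measured, 1 fell and 18 did not pass, while 3 fell adjusted over the list alone. The member that fell was Myocd, the coactivator of the smooth muscle programme, at -2.51 ± 0.57. Contractile genes had a median change of -1.32 and gave camera adjusted p = 2.74e-05, but adjusted p = 0.45 with an estimated correlation. Of 19 ion channels and tone regulators measured, 1 rose, 4 fell and 14 did not pass, while 2 rose and 9 fell adjusted over the list alone. The phosphodiesterase Pde5a changed by -1.86 ± 0.28 and the vasoconstrictor peptide gene Edn1 by 1.46 ± 0.34. Ion channel genes had a median change of -0.81 and gave camera adjusted p = 4.62e-05, but adjusted p = 0.273 with an estimated correlation. Of 23 immediate-early genes and early angiotensin targets measured, 1 rose, 3 fell and 19 did not pass, while 2 rose and 6 fell adjusted over the list alone. Atf3 changed by -2.39 ± 0.33, Jun by -2.05 ± 0.26 and Myc by 0.58 ± 0.13. Immediate-early genes had a median change of -0.79 and gave camera adjusted p = 0.00017, but adjusted p = 0.438 with an estimated correlation. The endothelial list did not pass (median 0.10, camera adjusted p = 0.0759), nor did those of T cells (median -0.13, camera adjusted p = 0.325) and neutrophils (median 0.16, camera adjusted p = 0.246). The means of the T cell and neutrophil lists lay under the negative control median on each day 0 and day 1 array, which leaves open whether these cells changed. The difference between positive and negative control features was lower on the 3 day 1 arrays than on every day 0 array beside all of these lists. The mean of the brown adipocyte genes was lower by 0.96 log2 units.

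Of the genes given in every comparison, the chemokine Ccl2 rose, as did the cytokine Il6 (2.39 ± 0.53, adjusted p = 0.0424). The angiotensin receptor gene Agtr1a (-0.01 ± 0.22), the converting enzyme gene Ace (-0.17 ± 0.62), the angiotensinogen gene Agt (0.10 ± 0.19), the oxidase gene Nox4 (-2.09 ± 0.50), the smooth muscle myosin gene Myh11 (-2.09 ± 1.07), the collagen gene Col1a1 (0.59 ± 0.32) and the chemokine gene Cxcl1 (0.35 ± 0.20) did not pass the limma test. Acta2, smooth muscle actin, lay at the ceiling of the scale on all day 0 and day 1 arrays, so no fold change can be given.

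In limma over all 12 arrays, 439 of 22065 genes rose and 360 fell at day 1 (Benjamini-Hochberg adjusted p under 0.05). Of these 188 and 155 changed at least 2-fold, and camera called 24 of the 40 lists. With an estimated correlation camera called 0 (6 at an unadjusted p under 0.05). Quantile normalization gave 476 genes, centred arrays 436 and the 6 arrays alone 209. Rises made up 54.9% of the calls, 57.1% after quantile normalization and 66.3% with arrays centred on their medians. With the mean of the adipocyte lists as a covariate limma called 0 genes (2788 at an unadjusted p under 0.05), while the control-feature covariate, chosen after seeing the data, kept 43 of the 51 calls named above. The adipocyte covariate ended the calls of oxidative phosphorylation (adjusted p = 0.695), clock (0.156), brown adipocytes (0.168), chemokines (0.0605), ion channels (0.695) and immediate-early genes (0.882), and the contractile list turned its direction (0.133). As the covariate is the mean of the adipocyte lists, the loss of the brown adipocyte call follows from its construction. In fry the unfolded protein response (0.137), contractile (0.182) and immediate-early lists (0.111) did not pass. Without day 0 replicates 1, 2 and 3 limma called 331, 200 and 138 genes, and 30, 22 and 18 of the 51 calls named above stayed. Without day 1 replicates 1 and 2 it called 187 and 101, and 21 and 16 stayed. Leaving out day 3 replicate 2 or 3 gave 475 and 482, with 40 and 38 kept.

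After 3 days 2593 genes passed the limma test against day 0, where 799 had at day 1. With the control-feature difference as a covariate, chosen after seeing the data, this order was reversed, with 464 and 1004 genes. That covariate differed from day 0 by -0.61 at day 3 and by -0.34 at day 1. Adjusting for it thus costs more precision at day 3, and the reversal does not decide which order is true. Serpina3n (5.20 ± 0.88), Prg4 (5.02 ± 0.93) and Esm1 (4.20 ± 0.38) again had the largest rises. Cxcl13, a chemokine that attracts B cells, rose by 3.51 ± 0.70, and the myeloid chemokines Ccl6 and Ccl9 rose by 3.19 ± 0.33 and 3.14 ± 0.41. Hspa1a (-6.32 ± 0.71) and Ccn1 (-4.87 ± 0.59), a matricellular protein induced by stretch and YAP signalling, had the largest falls. Fasn, the fatty acid synthase, changed by -4.00 ± 0.67 and Synpo2, an actin-binding protein of smooth muscle, by -3.98 ± 0.76.

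The remaining genes of the set that rose were Mrc1 (3.54 ± 0.54), Mmp3 (3.44 ± 0.32), Mki67 (3.34 ± 0.49), Timp1 (3.08 ± 0.40) and the small nucleolar RNAs Snord14e (3.45 ± 0.61) and Snord45b (2.95 ± 0.61). Those that fell were Pi15 (-4.74 ± 0.48), Dsp (-4.36 ± 0.48), the integrin ligand nephronectin Npnt (-4.35 ± 0.91), the protocadherin Pcdh7 (-4.20 ± 0.69), Ccdc3 (-3.98 ± 0.76), Cpe (-3.89 ± 0.70), the LIM-domain regulator Lmcd1 (-3.89 ± 0.51) and Gucy1b1 (-3.82 ± 0.42). Limma's adjusted p lay between 0.00102 and 0.0182 for these 24 genes, and all 3 treated arrays were beyond the day 0 arrays for each. Genes given in every comparison that passed were Nox4 (-2.59 ± 0.50), Ccl2 (1.52 ± 0.36) and Il6 (2.03 ± 0.53). Agtr1a (0.09 ± 0.22), Ace (-0.30 ± 0.62), Agt (0.28 ± 0.19), Myh11 (-3.54 ± 1.07), Col1a1 (0.72 ± 0.32) and Cxcl1 (0.16 ± 0.20) did not pass, and Acta2 averaged 19.75 ± 0.31 (SD, n = 3), close to the ceiling.

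At day 3, of 26 cell cycle genes measured, 19 rose and 7 did not pass, while 25 rose adjusted over the list alone. Top2a stood at 2.28 ± 0.31 and Prc1, a spindle midzone protein, at 1.63 ± 0.22. Cell cycle genes had a median change of 0.72 and gave camera adjusted p = 3.04e-13, but adjusted p = 0.385 with an estimated correlation. Of 21 monocyte and macrophage genes measured, 15 rose and 6 did not pass, while 19 rose adjusted over the list alone. The haemoglobin scavenger receptor Cd163 rose by 2.19 ± 0.22 and Ms4a6c by 2.07 ± 0.33. Macrophage genes had a median change of 1.10 and gave camera adjusted p = 5.34e-10, but adjusted p = 0.385 with an estimated correlation. Of 21 chemokine genes measured, 9 rose and 12 did not pass, while 10 rose adjusted over the list alone. Ccl12 was among them at 1.79 ± 0.25. Chemokines had a median change of 0.61 and gave camera adjusted p = 1.33e-05, but adjusted p = 0.385 with an estimated correlation. Of 26 collagen and matrix structure genes measured, 8 rose, 2 fell and 16 did not pass, while 10 rose and 3 fell adjusted over the list alone. Lox rose by 2.95 ± 0.36 and Col12a1 by 2.93 ± 0.61. Collagen genes had a median change of 0.54 and gave camera adjusted p = 0.0174, but adjusted p = 0.524 with an estimated correlation. Of 18 matrix proteases and inhibitors measured, 6 rose, 1 fell and 11 did not pass, while 8 rose and 2 fell adjusted over the list alone. Cathepsin S (Ctss) rose by 2.74 ± 0.74. Matrix proteases had a median change of 0.47 and gave camera adjusted p = 0.00871, but adjusted p = 0.385 with an estimated correlation. Of 17 unfolded protein response genes measured, 8 rose and 9 did not pass, while 9 rose adjusted over the list alone. The chaperone Hspa5 rose by 2.16 ± 0.49 and Creld2 by 1.97 ± 0.36. Unfolded protein response genes had a median change of 0.71 and gave camera adjusted p = 0.000116, but adjusted p = 0.449 with an estimated correlation. The list of inflammatory cytokines and acute phase genes did not pass at day 3 (median 0.63, camera adjusted p = 0.0524). The difference between positive and negative control features was 1.98 ± 0.14 on these arrays against 2.59 ± 0.05 at day 0.

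At day 3, of 19 contractile smooth muscle genes measured, 7 fell and 12 did not pass, while 14 fell adjusted over the list alone. Myocd stood at -3.40 ± 0.57, calponin (Cnn1) at -3.25 ± 0.82 and the myosin light chain Myl9 at -3.02 ± 0.74. Contractile genes had a median change of -2.12 and gave camera adjusted p = 4.48e-07, but adjusted p = 0.393 with an estimated correlation. Of 19 ion channels and tone regulators measured, 1 rose, 11 fell and 7 did not pass, while 1 rose and 13 fell adjusted over the list alone. The potassium channel subunit Kcnmb1 changed by -2.74 ± 0.49 and the phosphodiesterases Pde5a and Pde3a by -2.40 ± 0.28 and -2.15 ± 0.46. Ion channel genes had a median change of -1.33 and gave camera adjusted p = 1.25e-06, but adjusted p = 0.385 with an estimated correlation. Of 25 oxidative phosphorylation genes measured, 19 fell and 6 did not pass, while 21 fell adjusted over the list alone. Ndufa4 stood at -1.31 ± 0.33 and Sdhc at -0.96 ± 0.16. Oxidative phosphorylation genes had a median change of -0.71 and gave camera adjusted p = 3.04e-13, but adjusted p = 0.385 with an estimated correlation. Of 20 fatty acid oxidation genes measured, 11 fell and 9 did not pass, while 17 fell adjusted over the list alone. The dehydrogenases Hadh and Acadm changed by -1.75 ± 0.31 and -1.35 ± 0.33. Fatty acid oxidation genes had a median change of -0.65 and gave camera adjusted p = 1.45e-08, but adjusted p = 0.385 with an estimated correlation.

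At day 3, of 17 lipid synthesis genes measured, 6 fell and 11 did not pass, while 8 fell adjusted over the list alone. The malic enzyme Me1 stood at -3.13 ± 0.68 and Acly, which supplies acetyl-CoA, at -2.70 ± 0.74. Lipid synthesis genes had a median change of -0.86 and gave camera adjusted p = 4.61e-05, but adjusted p = 0.393 with an estimated correlation. Of 17 circadian clock genes measured, 1 rose, 8 fell and 8 did not pass, while 1 rose and 10 fell adjusted over the list alone. Nr1d1 stood at -2.50 ± 0.41, Dbp at -2.39 ± 0.33 and Per3 at -1.77 ± 0.34. Clock genes had a median change of -0.84 and gave camera adjusted p = 9.61e-06, but adjusted p = 0.385 with an estimated correlation. Of 13 white adipocyte genes measured, 2 fell and 11 did not pass, while 3 fell adjusted over the list alone. The triglyceride enzyme Dgat2 changed by -3.66 ± 0.71 and the lipase Lpl by -1.25 ± 0.35. White adipocyte genes had a median change of -0.64 and gave camera adjusted p = 0.00567, but adjusted p = 0.466 with an estimated correlation. Of 14 brown adipocyte genes measured, 1 rose, 5 fell and 8 did not pass, while 1 rose and 6 fell adjusted over the list alone. Brown adipocyte genes had a median change of -0.58 and gave camera adjusted p = 0.000253, but adjusted p = 0.385 with an estimated correlation. The interferon list did not pass at this time (median 0.24, camera adjusted p = 0.61), nor did heart muscle (median 0.18, camera adjusted p = 0.193). The control-feature difference was lower beside these lists on all 3 arrays.

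Limma called 1018 genes higher and 1575 lower at day 3 among 22065, with 352 and 576 changed at least 2-fold, and camera called 24 of the 40 lists. With an estimated correlation camera called 0 (3 at an unadjusted p under 0.05). Rises made up 39.3% of the calls, 29.3% after quantile normalization and 23% with arrays centred on their medians. With the adipocyte covariate limma called 15 genes, and 1 of the 54 calls named above stayed. The calls of contractile genes (adjusted p = 0.06), fatty acid oxidation (0.0762), brown adipocytes (0.139) and lipid synthesis (0.638) ended with it, and the white adipocyte list turned its direction (0.297). For the adipocyte lists this follows from the covariate, which is their own mean. The control-feature covariate gave 464 genes and kept 21 of the named calls, ended the call of lipid synthesis (0.162) and turned the white adipocyte list (0.983). Alone, the 6 arrays compared gave 4523 genes and ended the call of collagens (0.0548), as did fry (0.0641), which also ended that of white adipocytes (0.136). Without day 0 replicates 1, 2 and 3 limma called 1272, 1037 and 861 genes, and 39, 36 and 37 of the 54 calls named above stayed. Without day 3 replicates 2 and 3 it called 1038 and 702, and 40 and 33 stayed.

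At day 7 the contractile genes of smooth muscle showed the largest falls of any list, and the interferon, collagen and macrophage lists were higher. Their list calls did not hold in camera at adjusted p = 0.403 to 0.499 with an estimated correlation. Myh11, the myosin heavy chain of smooth muscle, went from 19.27 ± 0.04 at day 0 to 12.86 ± 2.16 (SD, n = 3 each), a change of -6.40 ± 1.07. Ccn1 (-7.55 ± 0.59), Hspa1a (-7.54 ± 0.71) and the integrin subunit Itga8 (-7.46 ± 1.28) changed still more. Aspn, which encodes asporin, a small leucine-rich matrix proteoglycan, had the largest rise at 4.83 ± 0.23. Oas2, an antiviral enzyme induced by interferon, rose by 3.95 ± 0.72.

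Other genes in the set that rose were Serpina3n (4.07 ± 0.88), Ctss (4.03 ± 0.74), Col12a1 (3.90 ± 0.61), Col8a1 (3.29 ± 0.45), the complement gene C4b (3.40 ± 0.58) and C1qtnf3 (3.63 ± 0.36), a secreted C1q-related protein. The interferon-induced family of Ifi204 (3.89 ± 0.73), Ifi211 (3.38 ± 0.70), Mndal (3.29 ± 0.45) and the pseudogene Ifi203-ps (3.44 ± 0.44) also rose; these are close paralogs, and their features could share signal. Genes that fell besides those above were Myl9 (-6.25 ± 0.74), Cnn1 (-5.82 ± 0.82), Synpo2 (-5.99 ± 0.76), the muscle LIM protein Pdlim3 (-5.22 ± 0.72), Npnt (-5.94 ± 0.91), Cpe (-6.02 ± 0.70), Pcdh7 (-5.60 ± 0.69) and the receptor phosphatase Ptprz1 (-5.32 ± 0.98). Adjusted p over these 24 genes ran from 3.1e-05 to 0.0123 in limma, with the 3 treated arrays beyond every day 0 array. Acta2 changed by at least -3.15 log2 units, a bound because the day 0 arrays lay at the ceiling of the scale, to 16.79 ± 1.80 (SD, n = 3, adjusted p = 0.0125 in limma).

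At day 7, of 19 contractile smooth muscle genes measured, 2 rose, 16 fell and 1 did not pass, while 2 rose and 17 fell adjusted over the list alone. Contractile genes had a median change of -3.70 and gave camera adjusted p = 4.92e-09, but adjusted p = 0.403 with an estimated correlation. Of 19 ion channels and tone regulators measured, 1 rose, 13 fell and 5 did not pass, while 2 rose and 14 fell adjusted over the list alone. Kcnmb1 changed by -4.57 ± 0.49, Gucy1b1 by -4.12 ± 0.42 and the prostacyclin synthase Ptgis by -3.15 ± 0.55. Ion channel genes had a median change of -1.51 and gave camera adjusted p = 1.1e-07, but adjusted p = 0.403 with an estimated correlation. Of 23 immediate-early genes and early angiotensin targets measured, 14 fell and 9 did not pass, while 18 fell adjusted over the list alone. Nr4a1 changed by -4.47 ± 0.82, Fos by -2.55 ± 0.45 and Jun by -2.42 ± 0.26. Immediate-early genes had a median change of -1.49 and gave camera adjusted p = 2.05e-07, but adjusted p = 0.403 with an estimated correlation. Of 25 TGF-beta and BMP signalling genes measured, 3 rose, 11 fell and 11 did not pass, while 3 rose and 13 fell adjusted over the list alone. The latency protein Ltbp1 stood at -3.66 ± 0.60, the target Id2 at -3.48 ± 0.51 and the growth factor Ccn2 at -3.27 ± 0.63. TGF-beta genes had a median change of -0.81 and gave camera adjusted p = 5.25e-05, but adjusted p = 0.403 with an estimated correlation. Of 25 oxidative phosphorylation genes measured, 19 fell and 6 did not pass, while 22 fell adjusted over the list alone. Atp5b changed by -1.20 ± 0.20. Oxidative phosphorylation genes had a median change of -0.64 and gave camera adjusted p = 6.03e-10, but adjusted p = 0.403 with an estimated correlation. Of 17 lipid synthesis genes measured, 1 rose, 8 fell and 8 did not pass, while 1 rose and 9 fell adjusted over the list alone. Fasn stood at -4.92 ± 0.67 and Me1 at -3.95 ± 0.68. Lipid synthesis genes had a median change of -0.80 and gave camera adjusted p = 0.000509, but adjusted p = 0.465 with an estimated correlation. Of 17 circadian clock genes measured, 1 rose, 11 fell and 5 did not pass, while 1 rose and 13 fell adjusted over the list alone. Nr1d1 changed by -2.32 ± 0.41 and Per2 by -1.57 ± 0.37. Clock genes had a median change of -0.95 and gave camera adjusted p = 1.62e-05, but adjusted p = 0.403 with an estimated correlation. The control-feature difference was 1.76 ± 0.49 on the day 7 arrays beside these lists, against 2.59 ± 0.05 at day 0.

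At day 7, of 21 interferon response genes measured, 16 rose and 5 did not pass, while 18 rose adjusted over the list alone. Ifit1 rose by 2.60 ± 0.69, Stat2 by 2.36 ± 0.55 and the transcription factor Irf7 by 2.15 ± 0.46. Interferon genes had a median change of 1.79 and gave camera adjusted p = 2.05e-07, but adjusted p = 0.465 with an estimated correlation. At day 0, 11 of the 21 lay under the negative control median on all 3 arrays. Their mean signal was 6.84 on day 7 replicate 1, 8.61 on replicate 2 and 8.43 on replicate 3, against 6.16 to 6.53 over the day 0 arrays. Of 21 monocyte and macrophage genes measured, 18 rose and 3 did not pass, while 20 rose adjusted over the list alone. The pore-forming protein gene Mpeg1 rose by 2.58 ± 0.26 and Lyz2 by 3.19 ± 0.38. Macrophage genes had a median change of 1.25 and gave camera adjusted p = 4.51e-08, but adjusted p = 0.403 with an estimated correlation. Of 26 collagen and matrix structure genes measured, 13 rose, 1 fell and 12 did not pass, while 13 rose and 3 fell adjusted over the list alone. Lumican (Lum) stood at 3.10 ± 0.45, Col1a1 at 2.12 ± 0.32 and the basement membrane collagen Col18a1 at -2.33 ± 0.53. Collagen genes had a median change of 0.87 and gave camera adjusted p = 0.00622, but adjusted p = 0.499 with an estimated correlation. Of 26 cell cycle genes measured, 8 rose, 1 fell and 17 did not pass, while 13 rose and 1 fell adjusted over the list alone. Mki67 rose by 1.87 ± 0.49. Cell cycle genes had a median change of 0.43 and gave camera adjusted p = 0.000749, but adjusted p = 0.542 with an estimated correlation. Of 21 chemokine genes measured, 8 rose and 13 did not pass, while 8 rose adjusted over the list alone. Ccl8 rose by 2.00 ± 0.39 and Cxcl13 by 2.17 ± 0.70. Chemokines had a median change of 0.63 and gave camera adjusted p = 0.00696, but adjusted p = 0.465 with an estimated correlation. The matrix protease list did not pass at day 7 (median 0.32, camera adjusted p = 0.394).

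At day 7, of 9 heart muscle markers measured, 5 rose and 4 did not pass, while 6 rose adjusted over the list alone. The cardiac myosin Myh6 rose by 2.56 ± 0.11, the troponin Tnnt2 by 1.91 ± 0.18 and the atrial light chain Myl7 by 1.51 ± 0.15. Heart muscle markers had a median change of 0.76 and gave camera adjusted p = 3.97e-05, but adjusted p = 0.403 with an estimated correlation. Myh6 and Myl7 lay under the negative control median of each day 0 array, so the sizes of these rises are approximate. Of 12 skeletal muscle markers measured, 6 rose, 1 fell and 5 did not pass, while 7 rose and 1 fell adjusted over the list alone. Tnnt3 stood at 1.16 ± 0.37 and Casq1 at -2.24 ± 0.41. Skeletal muscle markers had a median change of 0.52 and gave camera adjusted p = 0.0335, but adjusted p = 0.499 with an estimated correlation.

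Nox4 (-3.11 ± 0.50) and Ace (-1.90 ± 0.62, adjusted p = 0.0492) fell at day 7. Agtr1a (0.61 ± 0.22), Agt (0.58 ± 0.19), Ccl2 (0.63 ± 0.36), Il6 (0.75 ± 0.53) and Cxcl1 (0.11 ± 0.20) did not pass the limma test. Among other inflammatory genes, the oxidase subunit Cybb (1.78 ± 0.32), the chemokine receptor Ccr2 (2.23 ± 0.32) and the acute-phase gene Saa3 (2.14 ± 0.38) rose, and the prostaglandin synthase Ptgs2 fell (-3.47 ± 0.72). The endoplasmic reticulum chaperone Hsp90b1 (0.93 ± 0.24) and the glucocorticoid target Klf9 (-1.52 ± 0.48) passed, but took the other sign after quantile normalization (-0.033) and with the control-feature covariate (0.034). White adipocyte genes (median 0.12, camera adjusted p = 0.949), the endothelial list (median -0.17, camera adjusted p = 0.203), fibroblast and adventitia genes (median 0.01, camera adjusted p = 0.394) and the renin-angiotensin list (median 0.05, camera adjusted p = 0.949) did not pass.

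**Figure D2:**
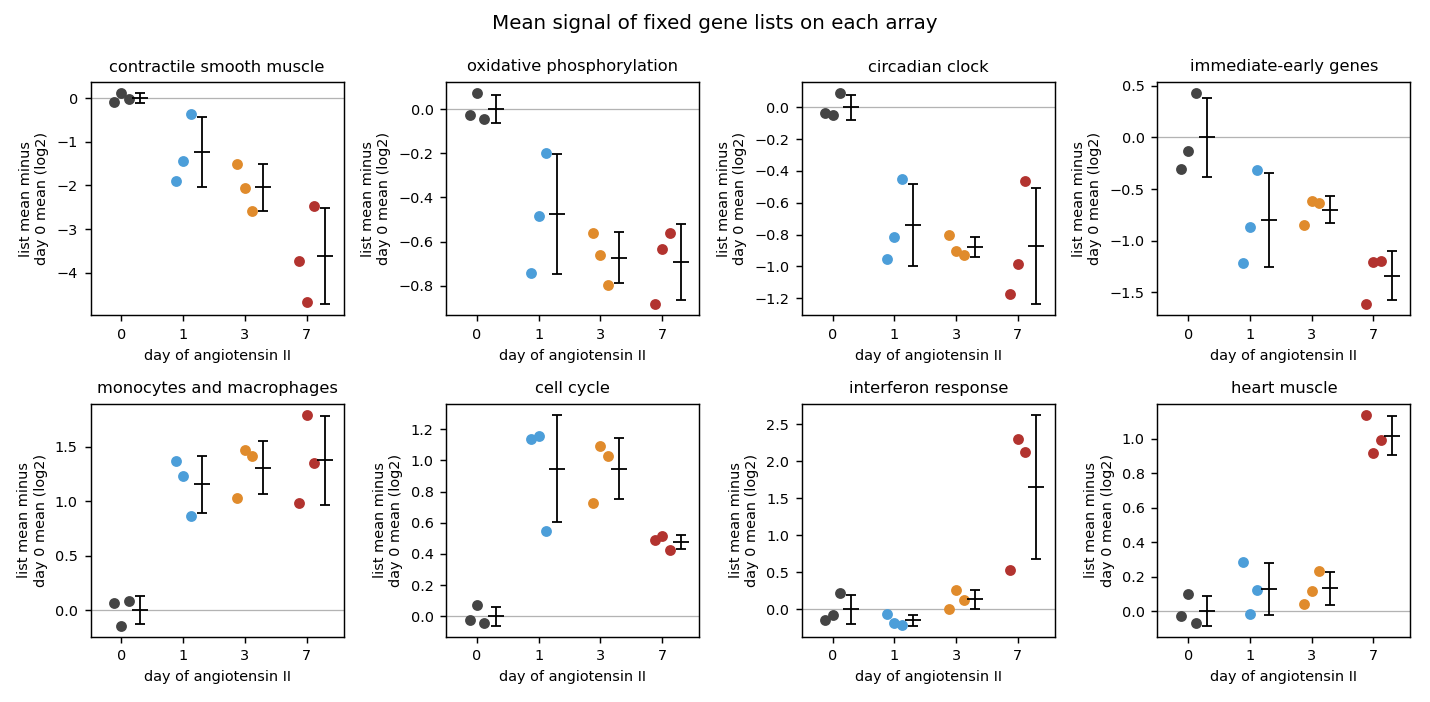
Mean signal of the measured members of 8 gene lists on each array, minus the mean of the day 0 arrays (y axes, log2), by day of angiotensin II (x axes), with a point per array and the group mean with its SD as a black bar beside the points. The contractile list is lower on all 9 treated arrays than on any day 0 array, and day 7 replicate 1 is the lowest of the day 7 arrays for the interferon list.

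Limma called 2668 genes higher and 2904 lower at day 7, with 981 and 1089 changed at least 2-fold, and camera called 25 of the 40 lists. With an estimated correlation camera called 0 (2 at an unadjusted p under 0.05). Rises made up 47.9% of the calls, 24.4% after quantile normalization and 20.7% with arrays centred on their medians. The median log2 change of all genes was 0.10, -0.09 and -0.18 under these scalings. With the control-feature difference as a covariate, chosen after seeing the data, the count was 771, with 29 of the 63 calls named above kept, and the calls of TGF-beta (adjusted p = 0.0918), lipid synthesis (0.459) and cell cycle (0.167) ended. With the skeletal muscle covariate it was 8643, with 57 kept, and the calls of collagens (0.207), chemokines (0.129) and skeletal muscle (0.441), whose own mean is the covariate, ended. It was 2325 with the adipocyte covariate (53 kept) and 2720 on the 6 arrays compared. The collagen call also ended without day 7 replicate 3 (0.0997). The skeletal muscle call ended after quantile normalization (0.0549), on the 6 arrays compared (0.0978), under the stricter filter (0.145) and over all features (0.0748). It ended too without day 7 replicate 2 (0.0744) or 3 (0.162), day 0 replicate 1 (0.0521) or 2 (0.055), or day 1 replicate 3 (0.059). Without day 0 replicates 1, 2 and 3 limma called 2837, 2965 and 2914 genes, and 55, 56 and 55 of the 63 calls named above stayed. Without day 7 replicates 1 and 2 it called 3385 and 3509, and 59 and 55 stayed.

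Day 3 was also compared directly with day 1. Limma called 0 genes, with 1775 at an unadjusted p under 0.05. Gene-by-gene array weights, added after seeing the data, called 1182, and leaving out day 7 replicate 1 called 1. The weight of day 1 replicate 2 was 4.17, against 0.42 and 0.66 for day 1 replicates 1 and 3, so the count of 1182 leans on that array. Camera called 7 of the 40 lists. Fry called 0 of them (3 at an unadjusted p under 0.05), and camera with an estimated correlation called 0 (1 at an unadjusted p under 0.05). Glucocorticoid response genes had a median change of 0.78 and gave camera adjusted p = 2.77e-05, but adjusted p = 0.84 with an estimated correlation. Of 15 measured, 2 rose adjusted over the list alone. Mesothelial markers had a median change of 0.35 and gave camera adjusted p = 0.00068, but adjusted p = 0.84 with an estimated correlation. Adjusted over the list alone 3 of their 5 genes rose. Of the 5, 3 lay under the negative control median on all day 1 arrays and 3 on all day 3 arrays. Genes with a mean signal between 5 and 6 had a median change from day 0 of 0.03 at day 1 and 0.17 at day 3, so the loss of signal range may account for part of it. Contractile genes had a median change of -0.89 and gave camera adjusted p = 0.00068, but adjusted p = 0.84 with an estimated correlation. Lipid synthesis genes had a median change of -0.62 and gave camera adjusted p = 0.00059, but adjusted p = 0.84 with an estimated correlation. Adjusted over the list alone 4 lipid synthesis genes fell. Oxidative phosphorylation genes had a median change of -0.21 and gave camera adjusted p = 0.000177, but adjusted p = 0.84 with an estimated correlation. The genes given in every comparison did not pass the limma test here.

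Without day 1 replicate 3 the calls of contractile genes (adjusted p = 0.101), lipid synthesis (0.0902) and oxidative phosphorylation (0.169) ended, and the last pair ended with the control-feature covariate too (0.109 and 0.119). The control-feature difference averaged 1.98 ± 0.14 at day 3 and 2.25 ± 0.29 at day 1 (SD, n = 3 each).

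Between day 3 and day 7 limma called 59 genes. Aspn rose by 4.13 ± 0.23 and C1qtnf3 by 3.78 ± 0.36, and the paraoxonase Pon1 (3.11 ± 0.40), the secreted angiopoietin-like protein Angptl1 (3.05 ± 0.25), Ifi203-ps (2.82 ± 0.44) and the matricellular thrombospondin Thbs2 (2.30 ± 0.27) rose with them. F3, tissue factor, the initiator of coagulation, changed by -4.36 ± 0.54. Esm1 (-2.94 ± 0.38), the lymphatic and macrophage hyaluronan receptor Lyve1 (-2.84 ± 0.28), Mmp3 (-2.68 ± 0.32), the mast cell carboxypeptidase Cpa3 (-2.07 ± 0.29) and Svep1 (-2.05 ± 0.30) fell. Adjusted p in limma ran from 0.00013 to 0.0416 over these 12 genes, and the 3 arrays of each group did not overlap.

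Of 9 heart muscle markers measured, 3 rose and 6 did not pass, while 6 rose adjusted over the list alone. Myh6 rose by 2.26 ± 0.11 and Tnnt2 by 1.48 ± 0.18. Heart muscle markers had a median change of 0.74 and gave camera adjusted p = 6.6e-10, but adjusted p = 0.301 with an estimated correlation. Among interferon genes none of 21 passed over all genes tested (Oas2 was at 2.72 ± 0.72), and all rose adjusted over the list alone. Their mean signal was 6.84, 8.61 and 8.43 on day 7 replicates 1, 2 and 3, against 6.31 to 6.57 at day 3. Most of the rise thus came from day 7 replicates 2 and 3. Interferon genes had a median change of 1.43 and gave camera adjusted p = 8.36e-18, but adjusted p = 0.352 with an estimated correlation. Of 26 cell cycle genes 6 fell adjusted over the list alone. Cell cycle genes had a median change of -0.43 and gave camera adjusted p = 3.66e-11, but adjusted p = 0.431 with an estimated correlation. In the unfolded protein response 13 of 17 fell adjusted over the list alone. Unfolded protein response genes had a median change of -0.79 and gave camera adjusted p = 6.6e-10, but adjusted p = 0.424 with an estimated correlation. Of 19 contractile genes 11 fell and 2 rose adjusted over the list alone. The contractile list had a median change of -1.38 and gave camera adjusted p = 3.98e-07, but adjusted p = 0.504 with an estimated correlation.

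Of 23 immediate-early genes and early angiotensin targets measured, 1 fell and 22 did not pass, while 4 fell adjusted over the list alone. The member that fell was Egr1 (-1.31 ± 0.19). Immediate-early genes had a median change of -0.60 and gave camera adjusted p = 1.11e-07, but adjusted p = 0.424 with an estimated correlation. Of 5 mast cell markers measured, 1 fell and 4 did not pass, while 4 fell adjusted over the list alone. Mast cell markers had a median change of -0.78 and gave camera adjusted p = 1.62e-05, but adjusted p = 0.352 with an estimated correlation. Adjusted over the list alone 7 of 12 skeletal muscle and 4 of 13 white adipocyte markers rose. Skeletal muscle markers had a median change of 0.60 and gave camera adjusted p = 4.6e-06, but adjusted p = 0.352 with an estimated correlation. White adipocyte genes had a median change of 0.67 and gave camera adjusted p = 0.000236, but adjusted p = 0.512 with an estimated correlation. The control-feature difference averaged 1.76 ± 0.49 at day 7 and 1.98 ± 0.14 at day 3.

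Limma called 25 genes higher and 34 lower between day 3 and day 7, with 19 and 27 at least 2-fold. Camera called 18 of the 40 lists while fry called 2, and camera with an estimated correlation called 0 (5 at an unadjusted p under 0.05). Rises were 42.4% of the calls, 32.1% after quantile normalization and 30.3% with arrays centred on their medians. The count was 272 and 186 without day 7 replicates 1 and 3, and 17, 16 and 10 without day 3 replicates 1, 2 and 3. It was 29 without day 0 replicate 3 and 1 on the 6 arrays compared. Of the 15 calls named above 15 and 14 stayed without day 7 replicates 1 and 3, 6, 6 and 5 without day 3 replicates 1, 2 and 3, and 13 without day 0 replicate 3. The count was 131 after quantile normalization, 325 with gene-by-gene weights, and 412, 797 and 377 with the adipocyte, skeletal muscle and control-feature covariates. The skeletal muscle list lost its call with its own mean as covariate (adjusted p = 0.734), as did white adipocytes with either tissue covariate (0.408 and 0.437), of which the adipocyte covariate includes their own mean.

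Over the whole time course, limma's F test over the 3 contrasts against day 0 called 3217 genes. It called 1340, 1130 and 1008 without day 0 replicates 1, 2 and 3, 1904 without day 1 replicate 2, and 2037 and 1980 without day 3 replicates 2 and 3. The control-feature covariate gave 935, the skeletal muscle covariate 5893 and gene-by-gene weights 8901. At every time against day 0, 301 genes rose and 333 fell, among them Serpina3n and Lyz2 on the rising side and Hspa1a, Cpe, Gucy1b1, Gstm1 and Jun on the falling side. Days 3 and 7 shared 691 rises and 1368 falls, against 123 and 207 for independent lists of these sizes, and days 1 and 3 shared 396 and 343, against 20.3 and 25.7. Fold changes correlated across genes, which are not independent replicates, at Pearson r = 0.801 for days 1 and 3, 0.839 for days 3 and 7 and 0.578 for days 1 and 7. Unchanged groups simulated with a shared day 0 group and independent errors per gene gave 0.495, 0.501 and 0.498 and 0 shared limma calls. The covariance was 0.18 for days 1 and 3 and 0.34 for days 3 and 7, against 0.03 and 0.04 simulated. The 3 day 0 arrays are too few to split, so part of the shared calls may come from the shared controls.

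**Figure D3:**
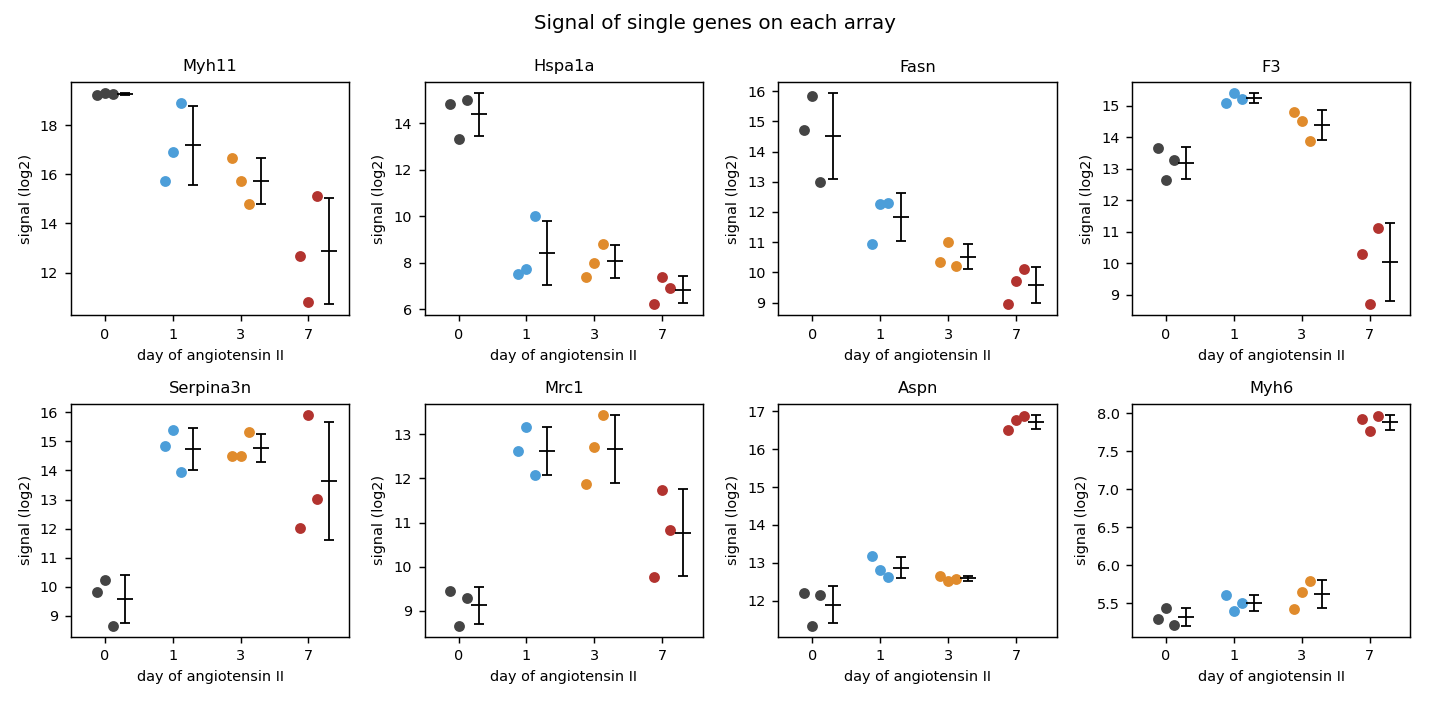
Signal of 8 genes on each array (y axes, log2) by day of angiotensin II (x axes), with a point per array and the group mean with its SD as a black bar beside the points. Myh11 averages 19.27 at day 0 and 12.86 at day 7, while Aspn lies at 16.72 and Myh6 at 7.88 on average at day 7.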

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

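The tests of tissue share, time of day and heart muscle below were chosen only after the results were seen, and the bound of the heart muscle test was changed after its value was known: by the first bound, on the median alone, that explanation would have been excluded. The change from day 0 differed between day 3 and day 7 in limma's test of that difference for 59 genes: it was higher at day 7 for 25 and lower for 34. Of these, 29 had opposite signs against day 0 at the 2 times, but only Thbs2 passed against day 0 at both. F3 had the largest such difference at -4.36, with means of 13.19, 15.24, 14.40 and 10.04 at days 0, 1, 3 and 7. Transcript clusters with no gene name were left out of the main comparisons and entered only the alternative over all features. Tested apart, 13, 53 and 852 of 20187 such clusters were higher than at day 0 at days 1, 3 and 7. Lower were 36, 193 and 585. Among the 22065 genes tested, 2668 were higher and 2904 lower at day 7.

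Whether chance alone gives such counts was checked by regrouping the arrays. Each pair of groups has 10 splits, too few for a share under 0.05. As many genes as observed came from 1 of the 10, the real grouping, at days 1, 3 and 7 against day 0 (highest other split 0 genes), 10 of 10 for day 3 against day 1 (highest other 0) and 1 of 10, again the real grouping, for day 7 against day 3 (highest other 1). Over time 1 of 100 splits, the real grouping itself, gave as many as 3217 genes, while the highest of the others gave 894. A chance split of the arrays is therefore unlikely to account for that count. Regrouping cannot separate infusion from array differences that follow the same groups, such as the control-feature difference.

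Of 19 contractile genes 16 fell at day 7 (list adjusted p = 0.403 with an estimated correlation). Their median of -3.70 lay at percentile 0 among 10000 random lists matched on mean signal, whose median was -0.04. A shift shared by genes of that signal therefore does not explain it alone. The random lists, here and below, drew unrelated genes, among them 198 with 1 value on all arrays. The percentile is thus not a p-value for the list. If less smooth muscle alone had been taken, the other resident cell types would have moved together. At day 1 endothelium and brown adipocytes differed by 1.26 log2 units (0.30 and -0.96). The gap was 1.26 to 1.91 on the day 1 arrays and 0.09 to 0.42 at day 0. These lists thus did not move together, but the amount of surrounding tissue taken is not given. The gap therefore cannot say how much smooth muscle was taken. With the adipocyte covariate the contractile list turned its direction at day 1 (camera adjusted p = 0.133) and Myh11 stood at 1.02. A lower share stays open at day 1. At day 7 the changes of the 4 resident lists ran from -0.66 to -0.03, closer together. None was higher, although a lower share of smooth muscle alone would raise all 4. A lower share may still be part of the fall there, and these lists do not decide it. A lower contractile programme per cell could account for part of the fall as well, which was not tested.

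Clock output genes had a median change of -1.29 at day 1, at percentile 0 of random lists matched on signal, so compressed signal range is not the cause alone. With an estimated correlation the clock list was not called at day 1, and the adipocyte covariate ended its call (camera adjusted p = 0.156). Collection at another time of day would move the activating arm the other way. The set tested for this, Arntl, Clock, Npas2, Cry1 and Nfil3, mixes activators with the repressors Cry1 and Nfil3. Its median was -0.13 at day 1, 0.14 at day 3 and -0.25 at day 7. As it does not measure the activators alone, it cannot decide the question, which stays open. The activator Arntl lay above all day 0 arrays on 3 of 3 arrays at each day, opposite to the output genes. Infusion itself may act on clock genes, and the hour of collection, not given in the sources used here, would separate these.

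Of 9 heart muscle markers 5 rose at day 7, among them Myh6 at 2.56 (list adjusted p = 0.403 with an estimated correlation). The list lay at percentile 99.96 of random lists matched on signal, so compressed range does not explain it alone. The other members with a value had a median change of 0.58 and an upper quartile of 0.81, with 2 that changed by at least 1. At day 0, however, 7 of the 11 members, Myh6 among them, averaged under the negative control medians, so their changes were poorly measured and heart muscle taken with the vessels stays open. Atrial tissue near the vessels could give such a mix, and so could induction in vessel cells. The atrial hormone gene Nppa, however, stayed under the negative control medians (4.53 at day 0 and 4.99 at day 7), and the atrial gene Sln changed by 0.76.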

How the results depend on the processing

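Of 183 values named in the text and past the threshold, 2 changed sign under an alternative, Hsp90b1 at day 7 after quantile normalization (-0.033) and Klf9 at day 7 with the control-feature covariate (0.034). Over 5446 values of named genes under the alternatives, 738 were no longer past the threshold, 25 were newly past it and 26 had the other sign. Filters, the variance estimate, the replicate block, the fit on the arrays compared and leaving out arrays of other days do not alter a fold change. The counts of signs therefore rest on the other alternatives only. Signal over background differs by group and limits what can be read for dim genes. The planned estimate of array weights did not converge and was replaced by the gene-by-gene estimate. Those weights ran from 0.242 on day 7 replicate 1 to 4.169 on day 1 replicate 2, so counts with weights lean on few arrays. Pseudocount choices, probe suffix removal and a covariate of 3' to 5' control signal were not run because the table gave no basis for them, and the F test was not run on 6 arrays. Where a cause is not named, the cause was not tested.

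At day 1 the count of 799 genes became 476 after quantile normalization, 436 with centred arrays, 3663 with gene-by-gene weights, 0 with the adipocyte covariate (2788 at an unadjusted p under 0.05), 209 on the 6 arrays compared and 101 to 1105 without an array. At day 3 the count of 2593 became 6564 with weights, 15 with the adipocyte covariate, 464 with the control-feature covariate, 4523 on 6 arrays and 702 to 3497 without an array. At day 7 the count of 5572 became 2325, 8643 and 771 with the adipocyte, skeletal muscle and control-feature covariates, 2720 on 6 arrays and 2837 to 7472 without an array. Day 3 against day 1 gave 1182 with weights and 0 to 1 without an array, in limma (1775 at an unadjusted p under 0.05 with all arrays). Day 7 against day 3 gave 131 after quantile normalization, 325 with weights, 412, 797 and 377 with the 3 covariates, 1 on 6 arrays and 10 to 272 without an array. Over time the F test gave 8901 with weights, 5893 and 935 with the skeletal muscle and control-feature covariates, and 1008 to 4308 without an array. A stricter threshold lowers a count by construction: adjusted p under 0.01 gave 96, 503, 1661 and 10 for days 1, 3, 7 and 7 against 3 and 581 over time, and changes of at least 2-fold numbered 343, 928 and 2070 against day 0.

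With an estimated correlation camera called 0 lists in every comparison, against 24, 24, 25, 7 and 18, while 6, 3, 2, 1 and 5 had an unadjusted p under 0.05 (days 1, 3 and 7, then 3 against 1 and 7 against 3). Fry called 15 lists at day 1, 0 for day 3 against day 1 (3 at an unadjusted p under 0.05) and 2 for day 7 against day 3. With the adipocyte covariate camera called 10 lists at day 1 and 13 at day 3, of which 7 and 11 had been called in the same direction without it. With the skeletal muscle covariate it called 16 at day 7, of which 16 had been. For day 3 against day 1 the count was 17 with no filter, 13 over all features, 13 with weights and 7 to 12 without an array.

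The other signs that turned belong to genes that did not pass. Agtr1a at day 1 was 0.29 with weights, 0.037 and 0.042 with the skeletal muscle and control-feature covariates and -0.23 to 0.12 without an array. Agtr1a at day 3 was -0.093 with centred arrays and -0.072 with the adipocyte covariate. Ace was 0.026 at day 1 and 0.050 at day 3 with the control-feature covariate, and -0.45 to 0.14 and -0.51 to 0.053 without an array. Myh11 at day 1 was 1.02 with the adipocyte covariate. Cxcl1 was -0.041 at day 1, -0.21 at day 3 and -0.063 at day 7 with that covariate, -0.008 and -0.16 at days 3 and 7 after quantile normalization, -0.026 and -0.17 with centred arrays, -0.026 at day 7 with the control-feature covariate, and -0.047 to 0.30 and -0.097 to 0.25 at days 3 and 7 without an array.

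With the replicate number as a replicate block limma called 820, 2794 and 5783 genes at days 1, 3 and 7, and 144, 297 and 607 calls of the fit without it were not among them. Of the calls named in the text 46 of 51, 53 of 54, 61 of 63 and, for day 7 against day 3, 13 of 15 stayed. Those that did not pass under the block were Ucp1, Ccdc3, C1qb, Dio2 and Myc at day 1, Lpl at day 3, Tnnt3 and Ace at day 7, and Ifi203-ps and Svep1 for day 7 against day 3. The numbers are not stated to pair the mice: of 18 same-numbered pairs, correlations ran from -0.506 to 0.662, 7 were over 0.1, and 7 of 12 arrays correlated best with an array of their own number. Under the block lipid synthesis at day 1 (0.0832), bone genes at day 3 (0.056), NK cells at day 7 (0.0637) and chemokines for day 7 against day 3 (0.0698) did not pass camera (adjusted p), and no other list call ended.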

Other observations

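At day 1, of 19 complement and coagulation genes measured, 1 rose and 18 did not pass, while 5 rose adjusted over the list alone. Complement genes had a median change of 0.40 and gave camera adjusted p = 4.07e-06, but adjusted p = 0.273 with an estimated correlation. Adjusted over the list alone 7 rose at day 3, and 2 over all genes. Complement genes had a median change of 0.49 and gave camera adjusted p = 0.00117, but adjusted p = 0.385 with an estimated correlation. Fatty acid oxidation genes at day 1 had 15 of 20 lower adjusted over the list alone and none over all genes tested. Fatty acid oxidation genes had a median change of -0.54 and gave camera adjusted p = 6.74e-10, but adjusted p = 0.273 with an estimated correlation. With the adipocyte covariate that list turned its direction (adjusted p = 0.577). Between day 3 and day 7, 1 TGF-beta and BMP gene fell of 25, and 9 fell adjusted over the list alone. TGF-beta genes had a median change of -0.44 and gave camera adjusted p = 8.62e-07, but adjusted p = 0.352 with an estimated correlation.

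The nerve genes Th and Dbh, enzymes of noradrenaline synthesis, were higher on replicate 2 of days 0, 1 and 7 and on day 7 replicate 3 than on the other 8 arrays. They were at 7.26 and 8.26 on day 0 replicate 2, 7.05 and 7.63 on day 1 replicate 2, 8.99 and 10.05 on day 7 replicate 2, and 7.78 and 8.38 on day 7 replicate 3. On day 0 replicate 1 they were at 5.50 and 5.73. The skeletal muscle gene Myh1 was at 5.48, 7.65 and 6.72 on day 7 replicates 1, 2 and 3, against 4.95, 4.95 and 5.46 at day 0. Poly-A spike controls averaged 5.36 ± 0.08 at day 0 and 4.67 at days 1, 3 and 7 (SD 0.11, 0.21 and 0.44, n = 3 each), with an exact permutation p = 0.1 for each. All 3 arrays of each treated group lay below every day 0 array, and the comparisons against day 0 cannot separate this difference from infusion.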
